A study of Caenorhabditis elegans with 24 samples.

How the data were processed

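Whole adult C. elegans of strain BA17, which carries the temperature-sensitive fem-1(hc17) allele, were grown at the restrictive temperature, imaged, and sorted one by one into age states by an image classifier, per the labels' protocols. At least 100 animals were pooled for each sample, and total RNA was labelled with Cy3 by a low-input linear amplification and hybridised to 1-colour Agilent expression arrays, per the labels' protocols. The 24 arrays lay on 6 slides of 4 arrays, per the file headers. The groups, the chronological day and the replicate number come from the labels. The labels state that 1 of the 24 arrays, replicate 6 of state 3 at day 8, was not included by the submitters, so 23 arrays entered the comparisons.

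The scanner files hold spot intensity on a linear scale, background-corrected by Agilent Feature Extraction 11.5.1.1, per the file headers, which name a ce6 genome build for the array design. The deposited value table holds 1 score per spot and array, with its scale unstated. Set against the scanner files, each of its 24 columns was the log10 processed intensity of 1 array, centred on the mean of its 45220 spots and divided by their SD, to within the rounding of the table. Its column medians lay between -0.24 and -0.12. In 7 of the 24 columns the values were those of another replicate of the same group than the column's label names, and in 0 columns those of another group, so group membership was not affected. Each array was taken from its own scanner file, and which of the mismatched replicate numbers is right is not known.

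From each scanner file, control spots and spots with an outlier flag were left out, spots of 1 probe were averaged, and log2 processed intensity minus the array's 75th percentile was used as the level. No spot was saturated. Between 57.4% and 74.2% of spots were well above background on the 23 arrays, and the number of arrays limits the precision. Of 43603 probes, 34539 were matched to 19855 genes through a table of locus tags and symbols (assembly WBcel235, used for names only), and 9064 were not matched and were left out. A probe was kept when it was well above background on at least 3 of the 23 arrays, which kept 31771 probes. The brightest kept probe stood for its gene, giving 15519 genes. For the list tests, 104 missing values were filled with their group mean. Genes with near-identical copies, which include the vitellogenins, the major sperm proteins and the hsp-16 genes, can share probe signal, so the level of a single copy is uncertain.

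Groups were compared in limma 3.58.1 (R 4.3.3) with a linear model over all 6 groups, lmFit and eBayes, and Benjamini-Hochberg adjustment over the 15519 genes at a threshold of 0.05. The comparisons were state 2 against state 1 at day 3, state 3 against state 2 at day 8, the later against the earlier day within each state, and state 3 at day 12 against state 1 at day 1 (the whole span). Moderated F-tests covered any state difference at a fixed day and any day difference at a fixed state, and a contrast tested whether the state difference at day 8 differed from that at day 3. Where a gene was not well above background on any array of a group, its fold is given as a lower limit: the mean log2 level of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own level and the lowest level among probes well above background.

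The 23 gene lists, fixed before the data were examined, covered yolk proteins, cuticle collagens, sperm genes, oocyte and eggshell, germline, early embryonic genes, pharyngeal muscle and gland, pharyngeal cuticle, body-wall muscle, neuron, FLP neuropeptides, intestine and digestive proteases, innate immunity, DAF-16 induced genes, insulin-like peptides, heat shock proteins and chaperones, proteasome, ribosomal proteins, mitochondrial respiratory chain, antioxidant enzymes, detoxification enzymes, lipid metabolism, and cell cycle and DNA replication. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 23 lists of a comparison. Camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, were alternatives. List medians are given relative to the median of all genes. Named genes were, for each comparison, the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, or the 3 smallest p in each direction where fewer than 10 genes passed, up to 4 members with the smallest p of each list called by camera, and fem-1, vit-2, the major sperm protein genes, sod-3, mtl-1 and hsp-16.2.

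Replicate numbers were not used as pairs: the deviations of same-numbered arrays of a same-day pair of groups from their group means were correlated across genes at r from -0.267 to 0.553. Genomic positions are not given, since no coordinates were at hand.

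A span score placed each array between state 1 at day 1 (mean 0) and state 3 at day 12 (mean 1), from the mean level of the 6963 genes that rose minus that of the 2500 that fell in a fit of those 6 arrays alone. Its differences between the other groups were tested with exact 2-sided permutation tests, adjusted over 3 tests.

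The code was tested on simulated data with the real genes' means and spread, in which 100 genes were changed 2-fold and 100 genes 4-fold in each comparison. At 2-fold it recovered 56% of the changed genes at day 3, 66% at day 8, 60% within state 1, 60% within state 2, 54% within state 3 and 59% over the span. At 4-fold it recovered 88%, 87%, 81%, 88%, 92% and 82% in the same order, and 3.16% to 5.88% of the calls were false. A shift of 0.5 log2 units of the proteasome list was called in each comparison, and of 22 unshifted lists camera called 1 in the span simulation and 0 in the others. These simulations drew genes independently, which the real arrays do not guarantee.

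Alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, other probe filters, the mean of a gene's probes, slide as a block, replicate number as a block, fits of only the 2 groups compared, the deposited value table, stricter thresholds, inclusion of the left-out array and the omission of each array in turn. The mean signal column planned for normexp is not among the columns of the scanner files used here, and the median signal was used in its place.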

Results

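The series asks whether age states assigned to worms from their images are also seen in their RNA levels. Whole adult C. elegans were compared from 6 groups: state 1 at day 1 (n = 3 arrays), state 1 at day 3 (n = 4), state 2 at day 3 (n = 4), state 2 at day 8 (n = 4), state 3 at day 8 (n = 5) and state 3 at day 12 (n = 3). Day 3 and day 8 each held 2 states, and each state was sampled on 2 days. Between 57.4% and 74.2% of the spots of these 23 arrays were well above background, and the 75th percentile of the signal ranged from 918 to 2415. The 3 arrays of state 2 at day 8 that lay on slide 4 had 74.2%, 69.9% and 68.8% of spots above background. The number of arrays limits the precision of each value. The labels do not say whether replicates were separate cultures, so each p-value measures only the spread between these samples. Log2 differences are given with the SE of the limma fit, and list medians relative to all genes.

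Over the whole span, from state 1 at day 1 to state 3 at day 12 (n = 3 against 3), many transcripts of yolk, cuticle, muscle and intestine fell. Of all called genes 73.9% were higher as reported, 61.6% with quantile normalization and 53.4% with median scaling. All 5 measured vitellogenin genes, which encode the yolk proteins made in the intestine, fell. On the log2 scale vit-1 changed by -7.47 ± 0.88 (adjusted p = 1.81e-06) and vit-2 by -2.60 ± 0.31 (adjusted p = 1.88e-06). Of 145 cuticle collagens 80 fell, 16 rose and 49 did not pass. Among those that fell were col-80 at -11.21 ± 2.06 and col-101 at -10.05 ± 1.20. Of 25 body-wall muscle genes 17 fell, 1 rose and 7 did not pass. They include the myosin heavy chain unc-54 at -3.82 ± 0.44 (adjusted p = 1.3e-06) and the paramyosin gene unc-15 at -2.63 ± 0.34. Of 23 intestinal genes 16 fell and 7 did not pass. Among those that fell were the protease genes asp-14 (-6.63 ± 0.67) and asp-13 (-5.94 ± 0.64) and the gut esterase ges-1 (-2.11 ± 0.22). Adjusted over the list alone, the counts were the same for yolk, body-wall muscle and intestine. For collagens they were 80 lower and 19 higher.

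Of 171 detoxification enzymes 91 fell and 26 rose over the span, including the glucuronosyltransferase genes ugt-53 (-5.46 ± 0.43) and ugt-6 (-4.72 ± 0.30, adjusted p = 7.76e-09). Of 69 lipid metabolism genes 36 fell, including the fatty acid elongase elo-5 (-5.78 ± 0.54) and the desaturase fat-2 (-2.24 ± 0.20), and 13 rose, including acs-16 (1.53 ± 0.18). Immune genes moved both ways. Of 72, 33 fell, as did spp-4 (-4.17 ± 0.43), and 17 rose. Those that rose include the antimicrobial peptide genes cnc-5, at least 49.5-fold higher, and cnc-1, at least 22.5-fold higher. Ribosomal protein genes rose in 70 of 77 cases by small amounts, as in rps-24 (0.79 ± 0.12). The largest rises were in C54F6.15, at least 749.9-fold, and the saposin-like gene spp-20, at least 240.5-fold. F40G12.5 rose at least 137-fold and the insulin-like gene ins-20 at least 107-fold, with Y57G11C.35 at 7.57 ± 0.64 and W04G5.11 at 7.51 ± 0.64. The largest falls were in irg-4, at least 2466-fold lower, col-80, the lysozyme gene ilys-5 (-10.58 ± 1.61), col-178 (-10.20 ± 1.47), col-101 and F56A4.2 (-10.04 ± 1.18). Adjusted over the list alone the counts were 91 lower and 26 higher for detoxification, 36 and 13 for lipid metabolism, 33 and 18 for immunity, and 71 higher for ribosomal proteins.

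Limma called 9512 of 15519 genes over the span, 7029 higher and 2483 lower, of which 4219 changed at least 2-fold. The groups did not overlap in 69.5% of all genes, against 10% by chance. Camera called lower yolk (median -2.98, adjusted p = 5.74e-06), collagens (-1.87, 4.41e-16), body-wall muscle (-1.75, 3.42e-11) and intestine (-2.099, 4e-10). It also called lower immunity (-1.18, 5.44e-07), detoxification (-1.14, 7.07e-15) and lipid metabolism (-0.81, 9.94e-09). With an estimated correlation the detoxification call held (adjusted p = 0.0339) and the others were lost, at adjusted p = 0.0901 for yolk, 0.0661 for collagens, 0.114 for body-wall muscle, 0.0667 for intestine, 0.141 for immunity and 0.0661 for lipid metabolism. Ribosomal proteins were called higher (median 0.23, adjusted p = 4.36e-05). With quantile normalization camera still called them higher (adjusted p = 0.0092), although their median was -0.02, of the opposite sign. The proteasome and the cell cycle list were also called higher (adjusted p = 0.0297 for each). Neither was called with median scaling (0.736 and 0.656, at medians that this scaling cannot change) or quantile normalization (0.101 and 0.186). Each of these calls was lost with an estimated correlation (adjusted p = 0.776 for each). The proteasome and cell cycle medians, -0.02 and -0.05, have the opposite sign to camera's direction; they were positive with normexp (0.10 and 0.06, adjusted p = 0.00384 and 0.00331) and quantile normalization (0.01 and 0.03). Of their members 24 of 33 and 25 of 36 rose, also adjusted over the list alone, such as pas-7 (0.83 ± 0.14) and the cyclin gene cye-1 (1.01 ± 0.14). Of all 15519 genes 7029 rose, and the list medians lay close to that of all genes. These counts therefore do not by themselves show a rise particular to the 2 lists. The scaling moved the median of all genes: it was 0.38 as reported, 0.11 with median scaling, 0.14 with quantile normalization and 0.26 with normexp. The count was 5278 with normexp, where the medians were -0.84 for collagens, -0.62 for immunity, -0.68 for detoxification and 0.37 for ribosomal proteins. The 3 arrays of state 3 at day 12 were alone on their slide; with slide as a block and the left-out array of that slide added, the count was 1157, and the called lists kept their calls, although the proteasome and cell cycle medians turned positive (0.04 and 0.28) and those of body-wall muscle and collagens were -2.84 and -2.87. That block links the groups through 1 array on each shared slide, which limits it. The proteasome and cell cycle calls were lost without state 1 replicate 2 (medians -0.07 and -0.05), the first also without state 3 replicate 2 (-0.04) and the second without state 3 replicate 3 (-0.06). The proteasome median was 0.02 without state 1 replicate 1 or 3 and -0.0037 without state 3 replicate 3. The cell cycle median was -0.02 without state 1 replicate 1 or 3 or state 3 replicate 2, and the ribosomal median was 0.13 without state 1 replicate 2.

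**Figure D1:**
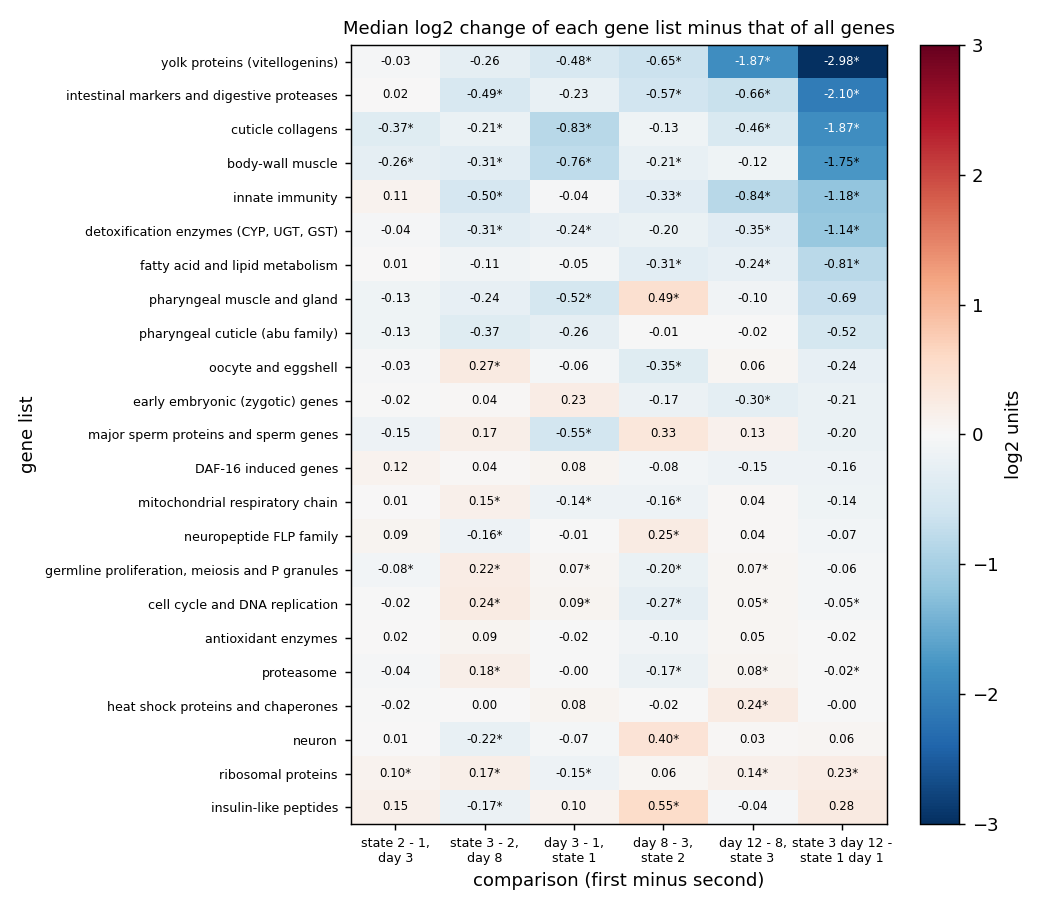
Median log2 change of each of 23 gene lists relative to all genes (colour) in the 6 comparisons (columns). Stars mark lists with a camera adjusted p under 0.05 at the preset correlation; 1 star, that of the detoxification enzymes over the span, held with an estimated correlation, and under normexp the medians of the ribosomal and mitochondrial lists within state 1 changed sign.

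Within state 1, from day 1 to day 3 (n = 3 and 4), the comparison asks what changed with days in worms that kept a young appearance. Of 145 cuticle collagens 7 fell and 138 did not pass (16 lower and 1 higher adjusted over the list alone), led by col-139 (-3.24 ± 0.70, adjusted p = 0.0459) and col-129 (-2.43 ± 0.43, adjusted p = 0.016). Of 25 body-wall muscle genes 16 were lower adjusted over the list alone, while the 25 did not pass over all genes. Among them was the giant muscle protein gene unc-89 at -0.89 ± 0.21 (adjusted p = 0.0626 over all genes). The C-type lectin gene clec-60 rose by 3.84 ± 0.73 (adjusted p = 0.0244), pitr-4 rose by 3.46 ± 0.59 and F09F3.8 by 2.83 ± 0.61. Ins-20 rose at least 5.91-fold, F12E12.2 at least 5.61-fold and cpg-24 at least 4.21-fold, the last turning to -0.11 with normexp. Besides the 2 collagens, the largest falls were in the cytochrome P450 gene cyp-14A3 (-2.76 ± 0.58), the lectin gene clec-206 (-2.76 ± 0.47), F40F8.12 (-2.22 ± 0.32) and R09E12.9 (-2.16 ± 0.39). Of 171 detoxification enzymes 4 fell and 167 did not pass (8 lower and 1 higher adjusted over the list alone), including gst-5 (-0.91 ± 0.16) and cyp-29A2 (-1.18 ± 0.22).

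Of 33 sperm genes 1 fell, msp-33 (-1.22 ± 0.25, adjusted p = 0.0373), and 6 were lower adjusted over the list alone. Of 36 germline genes 1 rose, the Argonaute gene csr-1 (0.69 ± 0.15, adjusted p = 0.0489), and 2 adjusted over the list alone. Camera called lower the collagens (median -0.83, adjusted p = 3.15e-19), body-wall muscle (-0.76, 3.71e-16), pharyngeal muscle and gland (-0.52, 0.000614), yolk (-0.48, 0.0426), sperm (-0.55, 1.96e-05) and detoxification (-0.24, 1.15e-07). It called higher the germline (0.07, 0.00165) and cell cycle lists (0.09, 0.00467). Ribosomal proteins (-0.15, 0.00165) and the respiratory chain (-0.14, 0.00467) were called lower, and with normexp both medians changed sign (0.12 and 0.13). With quantile normalization the ribosomal median stayed negative (-0.015) while camera gave the other direction (adjusted p = 0.195). The median of all genes was 0.09 as reported and -0.12 with normexp. Fry called none of the lists within state 1. Each of the 10 camera calls was also lost with an estimated correlation, at adjusted p = 0.108 for collagens, 0.116 for body-wall muscle, 0.129 for detoxification, and 0.604 for sperm and for pharyngeal muscle. The others had adjusted p = 0.662 for yolk and for the germline, 0.808 for the respiratory chain, 0.824 for the cell cycle and 0.901 for ribosomal proteins. Limma called 72 genes, 41 higher and 31 lower, with 2617 at an unadjusted p under 0.05; the groups did not overlap in 19.2% of all genes, against 5.71% by chance. The count was 0 with normexp, 0 in a fit of the 2 groups alone, 40 with median scaling, 42 without a probe filter and 127 with slide as a block; within slide 1, 47 genes were higher and 79 lower. The slide block and slide 1 both rest on 1 array of day 3, replicate 1. It fell to 0 without day 1 replicate 1, 35 without day 1 replicate 2, 12 and 10 without day 3 replicates 1 and 2, and rose to 204 without day 3 replicate 4. The germline and cell cycle calls were lost with slide as a block (medians -0.02 and 0.03), a test with that 1 array on a side, and the cell cycle call also without day 1 replicate 2 (0.04). The yolk and respiratory chain calls were lost without day 1 replicate 1 (-0.45 and -0.10), day 1 replicate 3 (-0.30 and -0.09) or day 3 replicate 1 (-0.38 and -0.11). The yolk call was also lost with normexp (-0.16, adjusted p = 0.327), with quantile normalization (-0.39, 0.123) and without day 3 replicate 2 (-0.40), and the ribosomal call without day 1 replicate 3 (-0.05). The germline median was 0.03 without day 1 replicate 2, 0.02 without day 3 replicate 4 and 0.14 without day 3 replicate 1, and the cell cycle median was 0.05 without day 3 replicate 2. Without day 1 replicate 2 the ribosomal and respiratory chain medians were -0.24 and -0.22, and without day 3 replicate 1 the pharyngeal muscle median was -0.33. Under the slide block the body-wall and pharyngeal muscle medians were -1.24 and -0.98. With normexp the germline, cell cycle and body-wall medians were 0.31, 0.34 and -0.44.

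Within state 2, from day 3 to day 8 (n = 4 and 4), some immune, lipid and intestinal genes changed, and 12 of 36 insulin-like peptide genes rose. Of 72 immune genes 21 fell and 11 rose (27 and 14 adjusted over the list alone). They include the thaumatin-like genes thn-1 (-2.99 ± 0.53, adjusted p = 0.00101) and thn-2 (-2.61 ± 0.50) and, upward, cnc-1, at least 4.57-fold. Of 69 lipid genes 27 fell and 6 rose (31 and 8 adjusted over the list alone). They include the stearoyl desaturase gene fat-7 (-2.69 ± 0.42, adjusted p = 0.000459), elo-6 (-1.97 ± 0.34) and, upward, acs-16 (1.21 ± 0.15). Of the 36 insulin-like peptide genes 24 did not pass (13 rose adjusted over the list alone), with ins-11 at least 7.29-fold higher and ins-16 at 1.55 ± 0.26. Of 27 neuron genes 10 rose and 1 fell (16 and 2 adjusted over the list alone), among them the syntaxin gene unc-64 (0.62 ± 0.11) and the calcium channel gene unc-2 (0.82 ± 0.21).

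Of 23 intestinal genes 9 fell and 2 rose (11 and 2 adjusted over the list alone), with asp-13 at -2.51 ± 0.56 and the intermediate filament gene ifb-2 at 0.69 ± 0.16. Oocyte and eggshell genes fell in 10 of 26 cases and rose in 2 (15 and 2 adjusted over the list alone), as in the eggshell gene cpg-3 (-0.67 ± 0.16) and, upward, perm-2 (0.40 ± 0.11). Of 36 germline genes 6 fell (4 adjusted over the list alone), including the P-granule helicase gene glh-2 (-0.47 ± 0.11), and of 36 cell cycle genes 4 fell (2 adjusted over the list alone), including cyb-3 (-0.40 ± 0.10). Top-2, 1 of these 4 (-0.44 ± 0.15), turned to 0.40 when the probes of a gene were averaged. Of 13 pharyngeal muscle and gland genes 4 rose, including tnc-2 (1.13 ± 0.23), with the same count adjusted over the list alone. Of 27 FLP neuropeptide genes 4 rose (3 adjusted over the list alone), including flp-21 (0.73 ± 0.19). Of 25 body-wall muscle genes 2 fell, unc-54 (-1.39 ± 0.38) and cpn-3 (-0.68 ± 0.19), also adjusted over the list alone. Of the 5 yolk genes 1 fell, vit-1 (-2.34 ± 0.77, adjusted p = 0.0339; 2 adjusted over the list alone). Among 33 proteasome genes 2 fell, pbs-4 (-0.30 ± 0.09) and rpn-5 (-0.30 ± 0.10), and among 44 respiratory chain genes 1 fell, cox-18 (-0.34 ± 0.11). None of these 3 passed adjusted over the list alone. Of all 15519 genes 2570 rose and 1047 fell within state 2. The shares of FLP genes that rose and of proteasome and respiratory chain genes that fell were below those shares, so these counts show no change particular to the lists. The largest rises were in C54F6.15, at least 52.5-fold, spp-20 (5.01 ± 0.95), clc-11 (4.78 ± 0.93), clec-17, at least 17.9-fold, Y40B10B.1 (4.29 ± 0.67) and Y119C1B.12, at least 18.2-fold. The largest falls were in oac-32 (-4.29 ± 0.87), K08D8.5 (-3.79 ± 0.84), clec-70 (-3.44 ± 1.17), spp-23 (-3.38 ± 0.89), the ammonium transporter gene amt-1 (-3.25 ± 0.62) and the lipase gene lipl-3 (-3.20 ± 0.94).

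Camera called lower the cell cycle (median -0.27, adjusted p = 7.03e-07), lipid (-0.31, 2.81e-06), oocyte (-0.35, 7.56e-06), germline (-0.20, 0.000199), proteasome (-0.17, 0.000409) and intestinal lists (-0.57, 0.00195). It also called lower the respiratory chain (-0.16, 0.00266), immunity (-0.33, 0.00742), body-wall muscle (-0.21, 0.0168) and yolk lists (-0.65, 0.0259). It called higher the insulin-like (0.55, 0.00189), neuron (0.40, 0.00934), FLP (0.25, 0.0128) and pharyngeal muscle lists (0.49, 0.0128). Each call was lost with an estimated correlation, at adjusted p = 0.402 for lipid, 0.613 for the respiratory chain, 0.635 for body-wall muscle, 0.718 for FLP and 0.605 for each of the others. Limma called 3617 genes, 2570 higher and 1047 lower, and the groups did not overlap in 21.4% of all genes, against 2.86% by chance. The scaling moved the median of all genes from 0.06 to -0.23 with median scaling and 0.29 with normexp, and 23.3% of 6267 called genes were higher with median scaling. With median scaling the immunity (adjusted p = 0.571), yolk (0.104) and FLP calls (0.0677) were lost. Their medians relative to all genes (-0.33, -0.65 and 0.25) could not change, since that scaling shifts all genes of an array by 1 amount. With quantile normalization the proteasome median was 0.0047 and its call was lost (0.673). With normexp the FLP median was smaller (0.08), while others were larger: -0.66 for cell cycle, -0.53 for germline, -0.72 for oocyte, -0.55 for proteasome, -0.51 for the respiratory chain, -0.63 for lipid, -0.50 for body-wall muscle, -1.04 for yolk and -0.85 for intestine. Quantile normalization gave smaller medians for cell cycle (-0.12), lipid (-0.20), oocyte (-0.22) and insulin-like genes (0.33). The count was 1900 with normexp, 1544 in a fit of the 2 groups alone, 165 with slide as a block and 0 within slide 3, where 1 array of day 8 met 3 of day 3; the slide block rests on the same arrays. It was 2333 and 2249 without day 3 replicates 2 and 4, and 1777 without day 8 replicate 3. With slide as a block the yolk (median -0.40), pharyngeal muscle (0.12), neuron (0.21), FLP (0.16) and immunity calls (-0.46) were lost. Without day 8 replicate 3 the yolk (-0.58), pharyngeal muscle (0.25), neuron (0.25) and FLP calls (0.14) were lost, and without day 8 replicate 4 the yolk (-0.54) and body-wall muscle calls (-0.13). Without day 3 replicate 3 the yolk (-0.58) and respiratory chain calls (-0.11) were lost, and the FLP call without day 3 replicate 1 (0.18) or 2 (0.19). The FLP median was 0.40 without day 3 replicate 3, the body-wall median -0.34 without day 8 replicate 2 and -0.37 with slide as a block, and the intestinal and immunity medians -0.37 and -0.20 without day 8 replicate 3.

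Within state 3, from day 8 to day 12 (n = 5 and 3), yolk, intestinal and detoxification genes were among those that fell. Of the 5 vitellogenin genes 4 fell (5 adjusted over the list alone), with vit-4 at -1.82 ± 0.22 (adjusted p = 0.000283) and vit-2 at -1.56 ± 0.28 (adjusted p = 0.00492). Of 171 detoxification enzymes 24 fell and 147 did not pass (36 lower and 2 higher adjusted over the list alone), including ugt-51 (-1.84 ± 0.21, adjusted p = 0.000239) and ugt-25 (-2.23 ± 0.40). Of 23 intestinal genes 7 fell (10 adjusted over the list alone), including asp-2 (-2.01 ± 0.41) and the gut transcription factor gene elt-7 (-0.61 ± 0.13). Of 69 lipid genes 11 fell (18 lower and 2 higher adjusted over the list alone), including the desaturase gene fat-3 (-1.70 ± 0.24, adjusted p = 0.00122) and elo-5 (-2.60 ± 0.49). Of 72 immune genes 8 fell and 3 rose (21 and 5 adjusted over the list alone), with spp-14 at -1.55 ± 0.26, the lysozyme gene lys-1 at -1.64 ± 0.36 and cnc-5, the largest rise, at 3.99 ± 0.58 (adjusted p = 0.00162).

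Of 40 heat shock and chaperone genes 1 rose (6 adjusted over the list alone), the small heat shock gene hsp-16.21 (2.29 ± 0.45, adjusted p = 0.0076). Of 145 collagens 2 fell, including col-158 (-1.56 ± 0.38), and 1 rose, col-10 (0.95 ± 0.19), which turned to -0.08 with slide as a block and the left-out array (1 fell and 1 rose adjusted over the list alone). Both collagen shares were below those of all 15519 genes, of which 544 fell and 136 rose. Other large rises were in C54F6.15 (2.91 ± 0.56), C25F9.2 (2.95 ± 0.59), fbxa-155 (2.92 ± 0.71), F02H6.4 (2.60 ± 0.67) and the odorant receptor gene odr-10 (2.55 ± 0.68). The largest falls were in pud-4 (-5.25 ± 0.97), ilys-5 (-5.21 ± 1.44), pud-2.1 (-4.93 ± 0.85), pugs-8 (-4.39 ± 0.79), sysm-1 (-4.17 ± 0.95) and mbug-1 (-3.90 ± 0.90). Camera called lower yolk (median -1.87, adjusted p = 6.32e-09), detoxification (-0.35, 6.32e-09), intestine (-0.66, 4.61e-08) and immunity (-0.84, 9.51e-08). It also called lower lipid (-0.24, 1.87e-07), collagens (-0.46, 3.33e-05) and early embryonic genes (-0.30, 0.0241), whose 35 members did not pass in either count. It called higher the heat shock (0.24, 9.63e-06), ribosomal (0.14, 9.63e-06), proteasome (0.08, 0.000214), cell cycle (0.05, 0.00636) and germline lists (0.07, 0.0071). The members of the last 4 lists did not pass in either count. Each call was lost with an estimated correlation, at adjusted p = 0.0883 for yolk, 0.0947 for detoxification and for lipid, 0.126 for intestine and 0.144 for immunity. The others had adjusted p = 0.317 for heat shock, 0.474 for collagens, 0.72 for proteasome and for the germline, and 0.747 for ribosomal, cell cycle and early embryonic genes. Limma called 680 genes, 136 higher and 544 lower; the groups did not overlap in 14.6% of all genes, against 3.57% by chance. The count was 100 with normexp, 86 in a fit of the 2 groups alone and 49 without day 12 replicate 3. With slide as a block and the left-out array added it was 473; the intestinal (median -0.26, adjusted p = 0.517) and lipid calls (-0.19, 0.168) were then lost, and the yolk median was -0.94 (0.0342), while the proteasome, cell cycle and germline medians were larger (0.37, 0.33 and 0.27), all resting on that 1 array of day 8. With quantile normalization the ribosomal median was -0.0018 and its call was lost (0.555). The early embryonic call was lost with normexp (median -0.16, adjusted p = 0.152) and quantile normalization (-0.21, 0.122), and with normexp the medians were smaller for collagens (-0.25), immunity (-0.48) and detoxification (-0.23) and larger for ribosomal (0.24), proteasome (0.18), germline (0.15) and cell cycle genes (0.14). The early embryonic call was also lost without day 8 replicate 1 (median -0.19) or 5 (-0.24) or day 12 replicate 2 (-0.16), the cell cycle call without day 8 replicate 5 (0.04) and the germline call without day 12 replicate 2 (0.02). The germline median was 0.05 without day 8 replicate 5 and 0.11 without day 12 replicate 1, and the ribosomal median 0.10 without day 8 replicate 5.

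**Figure D2:**
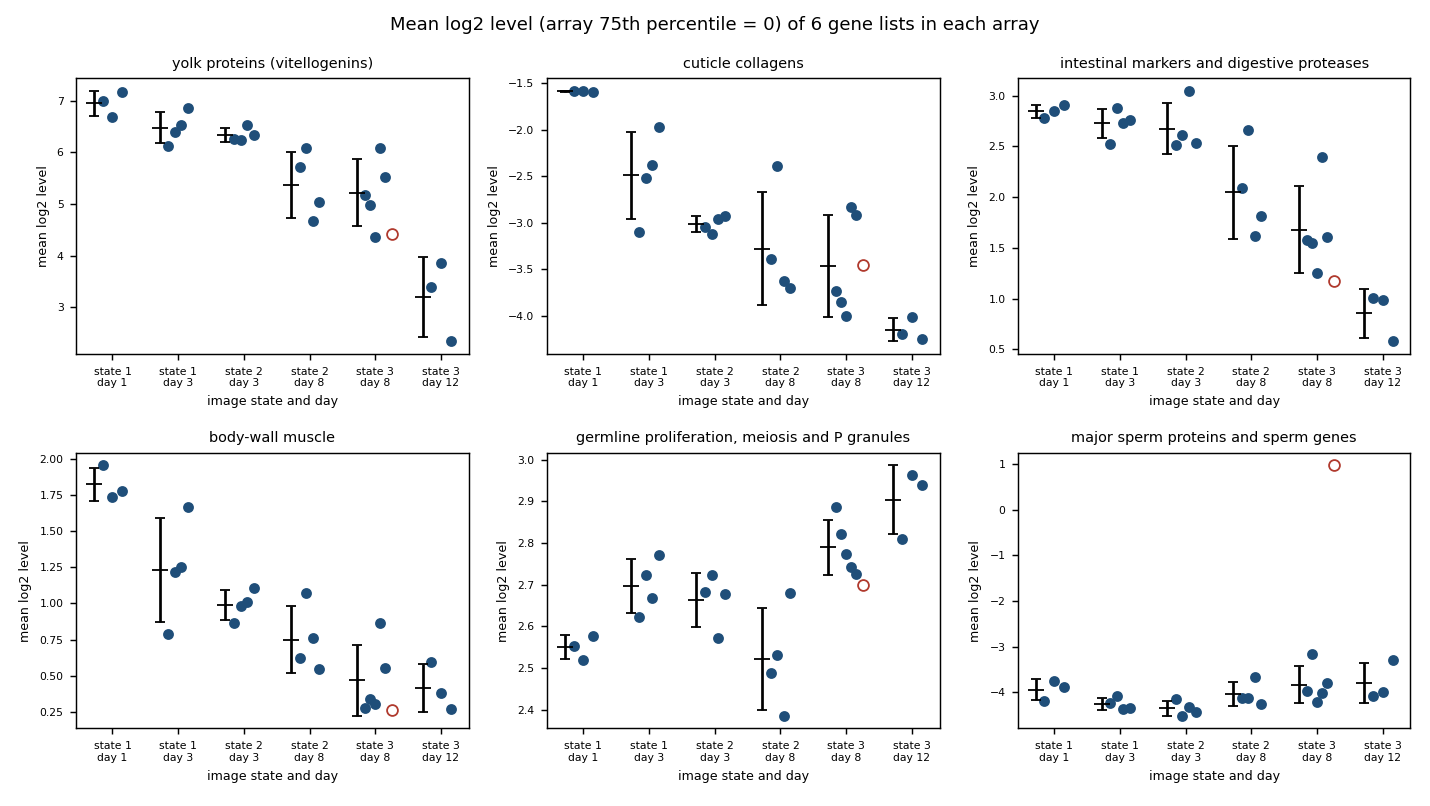
Mean log2 level of the genes of 6 lists on each array, by group in order of state and day, with bars for the mean and SD; the open red symbol is the day 8 array of state 3 that the labels leave out. The sperm list lies far higher on that array than on any other, with 31 of its 33 members above every other array.

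At day 3, worms of state 2 were compared with worms of state 1 of the same age (n = 4 and 4), which asks whether the image state is seen in RNA apart from days. No single gene passed: limma called 0 of 15519, with 438 genes at an unadjusted p under 0.05, fewer than the 776 that chance gives, and a smallest adjusted p of 0.908. The smallest p in the direction of state 2 belonged to Y71F9AM.8 (2.61 ± 0.55), F07B7.14 (2.19 ± 0.47) and F59B2.8 (0.63 ± 0.16), and in that of state 1 to F12E12.2 (-3.01 ± 0.60), Y47G6A.30 (-0.97 ± 0.26) and col-68 (-0.99 ± 0.27), none past the threshold. Camera placed collagens (median -0.37, adjusted p = 5.46e-12), body-wall muscle (-0.26, 6.86e-07) and the germline (-0.08, 0.00558) lower in state 2 and ribosomal proteins higher (0.10, 1.14e-05). Their 145, 25, 36 and 77 members did not pass in either count, and fry called none of the lists. Among the members, col-85 was at -3.26 ± 1.02, the myosin gene myo-3 at -0.31 ± 0.14, the Notch receptor gene glp-1 at -0.23 ± 0.13 and rpl-23 at 0.21 ± 0.13. Each call was lost with an estimated correlation, at adjusted p = 0.469 for collagens, 0.928 for body-wall muscle and 0.98 for the germline and ribosomal lists. The ribosomal call was also lost with slide as a block (median 0.04) and without state 2 replicate 3, where the median was still positive (0.0053) but camera gave the other direction (adjusted p = 0.943); the collagen and body-wall medians with slide as a block were -0.62 and -0.60. With normexp the collagen, germline and ribosomal medians were -0.10, -0.13 and 0.06. The body-wall call was lost without state 1 replicate 4 (-0.08), and the germline call without state 1 replicates 2 (-0.07) or 4 (-0.06) or state 2 replicate 3 (-0.03). The body-wall median was -0.41 without state 1 replicate 1 and -0.16 without state 2 replicate 1, and the ribosomal median 0.16 without state 2 replicate 2. Replicates 1 of both states were the closest of all 276 pairs of arrays (SD of 0.153 log2 units). The groups did not overlap in 1.84% of all genes, against 2.86% by chance, and 15 genes passed with slide as a block, 17 within slide 2 and 1 without state 2 replicate 2. The slide block and slide 2 both rest on 1 array of state 2, replicate 1.

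At day 8, worms of state 3 were compared with worms of state 2 of the same age (n = 5 and 4). As reported, some members of the germline, proteasome and respiratory chain lists were higher in state 3 by small amounts. Of all 15519 genes 1823 were higher and 323 lower. The joint limma F-test for any state difference at a fixed day passed for 0 genes, so it backed none of these calls. The same 4 arrays of state 2 enter the comparison within state 2 with the opposite sign. A fall there with days and a rise here with state are therefore not independent results. Of 36 cell cycle genes 22 were higher (32 adjusted over the list alone), including the cyclin gene cyb-1 (0.50 ± 0.11, adjusted p = 0.0202). Of 36 germline genes 15 were higher (25 adjusted over the list alone), including the meiotic axis gene him-3 (0.37 ± 0.09), and of 26 oocyte genes 10 (18 adjusted over the list alone), including the RNA-binding protein gene puf-5 (0.41 ± 0.09). Of 33 proteasome genes 14 were higher (24 adjusted over the list alone), including pas-7 (0.46 ± 0.11), and of 44 respiratory chain genes 9 (15 adjusted over the list alone), including the ATP synthase gene asb-1 (0.32 ± 0.08). Of 23 intestinal genes 3 were lower in state 3, ifb-2 (-0.62 ± 0.15), the intestinal actin gene act-5 (-0.56 ± 0.17) and the gut transcription factor gene elt-2 (-0.43 ± 0.13). Of 72 immune genes 1 was lower, irg-7 (-1.23 ± 0.28). Both counts were the same when adjusted over the list alone.

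Of 171 detoxification enzymes 12 were lower and 2 higher (2 lower adjusted over the list alone), with cyp-35B2 the lowest (-2.18 ± 0.38) and cyp-35B1 at -1.33 ± 0.34. Of 77 ribosomal genes 1 was higher, rpl-22 (0.35 ± 0.10), of 27 neuron genes 1 was lower, rab-3 (-0.37 ± 0.11), and of 145 collagens 1, col-34, at least 1.57-fold. None of these 3 passed adjusted over the list alone. The ribosomal and collagen shares were below those of all genes, of which 1823 of 15519 were higher and 323 lower. The largest positive differences were in the chemoreceptor-family gene srv-19, at least 4.18-fold, F52D4.1 (1.21 ± 0.23), the thioredoxin reductase gene trxr-1 (0.79 ± 0.23), elli-1 (0.78 ± 0.22), idpb-4 (0.75 ± 0.24) and ceh-83 (0.73 ± 0.21). Besides cyp-35B2, the largest negative differences were in sri-17, at least 3.05-fold, F45D11.1, at least 2.15-fold, F45D11.14 (-1.72 ± 0.41), K11H12.4 (-1.71 ± 0.45) and C34H4.2, at least 2.72-fold; without a probe filter F45D11.1 turned to 0.88. Camera called higher the cell cycle (median 0.24, adjusted p = 1.69e-11), proteasome (0.18, 1.45e-08), germline (0.22, 4.14e-08), oocyte (0.27, 1.23e-06), ribosomal (0.17, 2.28e-05) and respiratory chain lists (0.15, 4.33e-05). It called lower detoxification (-0.31, 9.11e-09), immunity (-0.50, 1.37e-05), intestine (-0.49, 4.33e-05) and body-wall muscle (-0.31, 0.000204). It also called lower neuron (-0.22, 0.000409), collagens (-0.21, 0.00105), FLP (-0.16, 0.0149) and insulin-like genes (-0.17, 0.0149). The members of the body-wall muscle, FLP and insulin-like lists did not pass in either count. Each call was lost with an estimated correlation, at adjusted p = 0.24 for detoxification, 0.359 for cell cycle, germline, intestine and immunity and 0.367 for oocyte and proteasome. The others had adjusted p = 0.409 for neuron, 0.433 for the respiratory chain, collagens, body-wall muscle and insulin-like genes, 0.632 for ribosomal proteins and 0.682 for FLP. In the 4 arrays of slide 4, 1 of state 3 and 3 of state 2, the medians were 0.30 for cell cycle, 0.23 for germline, 0.39 for oocyte and 0.20 for proteasome. With quantile normalization 36.3% was left of the mean difference of 131 genes of these 4 lists, and 7 of 7 lists of somatic tissues averaged higher in state 2 as reported, 5 of 7 without state 2 replicate 3 and 6 of 7 without replicate 2. With that normalization the ribosomal and respiratory chain medians were -0.0050 and 0.012, and both calls were lost (camera adjusted p = 0.757 and 0.36). The proteasome median was then 0.039 (camera adjusted p = 0.0221). On slide 4 the medians were -0.56 for intestine and -0.70 for immunity, and the insulin-like call was lost (adjusted p = 0.0796). The collagen (-0.02) and ribosomal calls (0.09) were lost without state 2 replicate 2, the FLP (-0.07) and insulin-like calls (-0.13) without state 2 replicate 3, and the FLP call also without state 3 replicate 3 (-0.11). Without state 2 replicate 2 the intestinal and immunity medians were -0.21 and -0.25. Without state 2 replicate 3 the medians were 0.17 for oocyte, 0.13 for germline, 0.11 for proteasome, 0.09 for the respiratory chain, 0.15 for cell cycle and -0.12 for neuron. The collagen median was -0.32 without state 2 replicate 4, and -0.14, -0.13 and -0.31 without state 3 replicates 2, 3 and 4. Immunity was at -0.33 without state 3 replicate 1 and intestine at -0.29 without state 3 replicate 3. Without the 3 arrays of state 2 on slide 4 the neuron (-0.10, adjusted p = 0.0531), FLP (-0.10) and insulin-like calls (-0.10) were lost, and the collagen and oocyte medians were -0.12 and 0.18. Under the slide block the body-wall, collagen, neuron, FLP and insulin-like medians were -0.62, -0.41, -0.39, -0.29 and -0.26. With normexp the medians were -0.02 for FLP, -0.12 for neuron, -0.11 for body-wall muscle, -0.30 for intestine, -0.29 for immunity and -0.18 for detoxification, and from 0.37 to 0.50 for the 6 lists called higher.

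Limma called 2146 genes at day 8, 1823 higher and 323 lower in state 3, of which 75 differed at least 2-fold, and the smallest adjusted p was 0.0202. The groups did not overlap in 13.6% of all genes, against 1.59% by chance. The median of all genes was 0.06 as reported and -0.10 with normexp. The count was 0 with normexp, 0 in a fit of the 2 groups alone, 0 within slide 4, 12 with slide as a block (4 higher and 8 lower, on 1 array of state 3), 10 with quantile normalization (3 higher and 7 lower) and 11 without the 3 arrays of state 2 on slide 4. It was 0 without state 2 replicate 3, without state 3 replicate 1 or without state 3 replicate 2, 618 without state 2 replicate 1 and 1385 without state 3 replicate 3. As reported, 4909 genes had an unadjusted p under 0.05.

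A score placed each array between the ends of the span and used no array of the 4 middle groups to choose its genes. At day 3 state 2 scored 0.264 ± 0.0276 (SD, n = 4) and state 1 0.188 ± 0.0744 (SD, n = 4), a difference of 0.0759 (exact 2-sided permutation p = 0.114, adjusted p = 0.171), with 4 of 4 arrays of state 2 above the mean of state 1. At day 8 state 3 scored 0.717 ± 0.115 (SD, n = 5) and state 2 0.583 ± 0.168 (SD, n = 4), a difference of 0.134 (exact permutation p = 0.198, adjusted p = 0.198), with 4 of 5 above. Neither state difference passed; without state 1 replicate 1 the day 3 difference was 0.111 (adjusted p = 0.0429). Within state 2 the score was 0.319 higher at day 8 than at day 3, with 4 of 4 arrays above, at the smallest p that 70 regroupings allow (exact permutation p = 0.0286, adjusted p = 0.0857), which did not pass after adjustment. Of the 1823 genes higher in state 3 at day 8, 1434 were also higher over the span, against 825.7 if the calls were independent, and of the 323 lower genes 191 were also lower, against 51.7. The calls are not independent, since both come from 1 fit with the same gene variances and array scaling. The excess is therefore no test of a shared change, and few or no day 8 calls were left with quantile normalization or normexp. Across genes, which are not independent replicates, the state difference and the span change were correlated at r = 0.394 for day 3 and 0.318 for day 8.

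**Figure D3:**
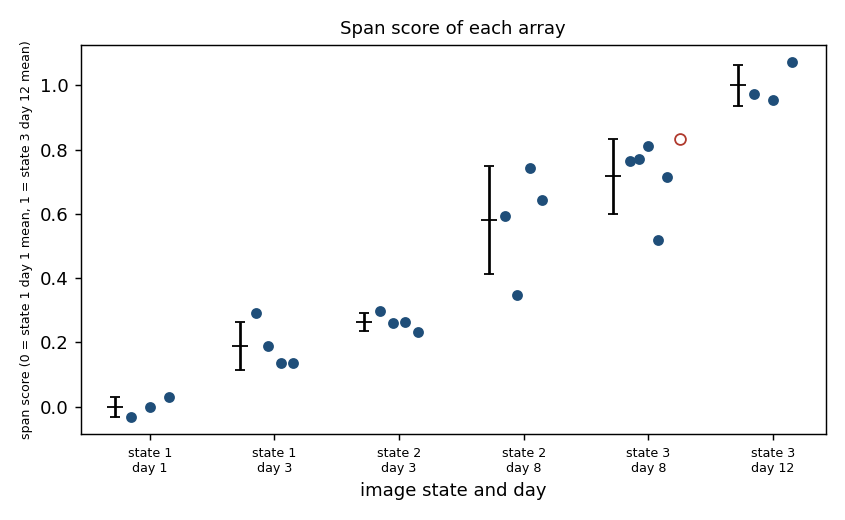
Span score of each array (0 = mean of state 1 at day 1, 1 = mean of state 3 at day 12) by group, with bars for the mean and SD; the open red symbol is the array that the labels leave out. The scores of the day 3 arrays lay between 0.134 and 0.299, and those of the day 8 arrays, the left-out one included, between 0.349 and 0.832.

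In joint tests over all genes, 0 genes passed the limma F-test for any state difference at a fixed day (3761 at an unadjusted p under 0.05, smallest adjusted p = 0.0688), and 3806 passed that for any day difference at a fixed state. The counts have different power, since the tests differ in groups and degrees of freedom. The difference between the state differences of day 3 and day 8 passed for 0 genes by limma (2647 at an unadjusted p under 0.05). The state count was 575 for probes above background on all 23 arrays, 23 with slide as a block and the left-out array added and 1205 without state 3 replicate 4 of day 8; the day count was 904 with normexp and 1096 with that slide block. Of the genes chosen in advance, fem-1, which is needed for male development and sperm formation and carries the strain's mutation, passed in no comparison (0.02 ± 0.11 over the span, adjusted p = 0.903). The DAF-16 target sod-3, a superoxide dismutase gene, also passed in none (-0.22 ± 0.26 over the span), while the metallothionein gene mtl-1 (1.52 ± 0.45, adjusted p = 0.00647) and the heat shock gene hsp-16.2 (1.26 ± 0.44, adjusted p = 0.0181) rose over the span.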

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

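Among the tests below, those of array-wide scaling and of embryos for the sperm genes, and those of slide 4 and of the germline and somatic balance at day 8, were chosen only after the result was seen; the others were fixed beforehand.

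The array of state 3 at day 8 that the labels leave out carried a strong sperm signal: the 33 sperm genes lay a median of 5.92 log2 units above the other 5 arrays of its group, and msp-78 stood at 3.79 against a mean of -2.28. Of the 83 genes more than 2 log2 units above every other array, 23 were in the sperm list. Array-wide scaling or background was argued against, since the list lay at the 100th percentile of random lists matched on level, whose highest median was 0.846. Fertilised animals carrying embryos stay open. The early embryonic list stood at -4.58, within the -4.77 to -3.74 of the other 5 arrays. Of its 35 members 26 were well above background (16 to 27 on the others), so the list had signal on those arrays too. No array known to hold embryos was at hand to show that it would rise with them. Males in the sample also stay open, since 9 male genes of neurons and seminal fluid averaged -3.78, above the -5.25 to -4.27 of the other arrays but by less than their range. All 9 were well above background on that array, against 4 to 7 on the other 5. Of all its spots 74.6% were well above background, against 57.4% to 66.5% on the other 5. Counts of genes above background can thus be higher there for any dim list and do not single out male or embryonic genes. A mix-up with an outside sample was not tested.

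The state difference at day 8 differed from that at day 3 for 11 lists by camera on the difference itself, although none of these calls held with an estimated correlation (adjusted p from 0.396 to 0.792). The median difference, given here not relative to all genes (whose median was 0.03), was 0.34 for oocyte, 0.33 for germline, 0.32 for cell cycle, 0.26 for proteasome and 0.19 for respiratory chain genes. On the same scale it was -0.40 for immunity, -0.31 for intestine, -0.27 for insulin-like peptides, -0.23 for detoxification, -0.20 for FLP neuropeptides and -0.18 for neuron genes.

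The shift at day 8 within that pattern was followed in 131 genes of the oocyte, germline, cell cycle and proteasome lists, which averaged 3.66 ± 0.123 (SD, n = 4) in state 2 and 3.94 ± 0.0862 (SD, n = 5) in state 3, a difference of 0.2802. State 2 at day 8 had the lowest mean of all groups, below the 3.83 ± 0.036 (SD, n = 4) of state 2 at day 3. Its arrays therefore give both this shift and the fall of these lists within state 2. Slide 4, which held 3 of the 4 arrays of state 2, stays open: with slide as a block the shift was 0.395 (95% interval 0.163 to 0.627), but this rests on the only array of state 3 on that slide, replicate 1. Scaling between arrays also stays open, since quantile normalization left 36.3% of the shift, while normexp gave list medians from 0.40 to 0.50 relative to all genes. A different balance of germline and somatic RNA also stays open: 7 of 7 somatic lists were higher in state 2, by 0.0842 to 0.368, but 5 of 7 without state 2 replicate 3 (pharyngeal muscle at -0.15 and FLP at -0.04) and 6 of 7 without replicate 2 (collagens at -0.11). Whether the age state itself underlies the shift was not tested.

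Single arrays stood apart from their group in 9 of 100 tests of list means, span score and spots above background, where chance gives about 1 in 20 for each test. The tests were not independent, since the same arrays entered many of them, so the 9 show no excess over chance. The ratio is the gap to the nearest array over the group's range. In state 1 at day 3, replicate 1 was low for pharyngeal muscle (-1.62 against -1.24 to -1.21, ratio 0.911) and replicate 2 high for neuron genes (-1.85 against -2.05 to -2.02, ratio 0.873). In state 2 at day 3, replicate 3 was apart in 5 lists: low for the abu family (-5.41, ratio 0.913) and the cell cycle (3.58, ratio 0.855), and high for FLP (0.14, ratio 0.883), respiratory chain (3.69, ratio 0.881) and neuron genes (-1.82, ratio 0.846). Neuron genes were also high in state 2 at day 8 replicate 3 (-1.23 against -1.77 to -1.71, ratio 0.891) and in state 3 at day 8 replicate 5 (-1.54 against -1.88 to -1.81, ratio 0.774).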

How the results depend on the processing

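The alternatives with array position as a block, with unmatched probes kept, with the replicate numbers of the value table, without arrays of the closest pair or of slide 4, and with slide as a block plus the left-out array were chosen only after seeing the data. Of the 64 list calls outside the test of the difference, 60 kept their direction and their side of the threshold with normexp, 59 with median scaling, 43 with quantile normalization, 54 with the value table and 64 with the replicate block. With fry 28 did: 6 at day 8, 6 in state 2, 6 in state 3, 10 over the span, and 0 at day 3 and in state 1. With an estimated correlation 1 did. Quantile normalization ended the calls of the ribosomal list at day 3, day 8 and in state 3, of the respiratory chain at day 8 and in state 2, of collagens and insulin-like peptides at day 8, and of the germline list at day 3 and within each state. It also ended those of yolk in states 1 and 2, of body-wall muscle, neuron and proteasome in state 2, of early embryonic and cell cycle genes in state 3, and of proteasome and cell cycle over the span. Not every median shrank alike. In state 2 yolk was at -0.58 against -0.65 as reported and body-wall muscle at -0.16 against -0.21. Neuron was at 0.20 against 0.40 and proteasome at 0.0047 against -0.17. Of the named genes past the threshold, 106 kept their direction and passed with normexp and 100 no longer passed; 152 and 55 did so with quantile normalization, and 89 and 118 in fits of the 2 groups alone. With slide as a block 15 passed and 103 no longer did, over the 4 comparisons it allows. The signal over background limits dim genes, whose folds are lower limits. The cause of the changes below was not tested, except that fewer arrays entered the fits within slides, of 2 groups, and with arrays left out. Joint tests and the span score were not run with slide as a block without the left-out array, and list tests were not run with slide as a random block.

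In the order day 3, day 8, state 1, state 2, state 3 and span, the counts that moved by over 1.5 times were as follows. With normexp they were 0 at day 8, 0 in state 1, 1900 in state 2, 100 in state 3 and 5278 over the span, with 904 genes for any day difference; cpg-24 in state 1 turned to -0.11, and the ribosomal and respiratory chain medians in state 1 to 0.12 and 0.13. The proteasome and cell cycle medians over the span turned positive, at 0.10 and 0.06, and the calls of yolk in state 1 and early embryonic genes in state 3 ended, each at a median of -0.16. With quantile normalization day 8 had 10 genes, and camera turned the direction of the ribosomal list in state 1 (adjusted p = 0.195), while its median stayed negative at -0.015. With median scaling state 1 had 40 genes and state 2 had 6267, and the calls of immunity, yolk and FLP in state 2 and of proteasome and cell cycle over the span ended. The medians of these lists relative to all genes could not change, since median scaling shifts all genes of an array by 1 amount. Without a filter day 8 had 1148 genes, state 1 had 42, and F45D11.1 at day 8 turned to 0.88. For probes above background on all 23 arrays 575 genes passed for any state difference. With the mean of a gene's probes 2 genes passed for any state difference, and top-2 in state 2 turned to 0.40. With the value table day 8 had 716 genes, state 1 had 31, and any day difference 2518. In fits of the 2 groups alone day 8 had 0 genes, state 1 had 0, state 2 had 1544 and state 3 had 86. With the threshold at 0.01 the counts were 0 at day 8, 10 in state 1, 1519 in state 2, 197 in state 3 and 1324 for any day difference; with at least 2-fold also required they were 75, 41, 1441, 331 and, over the span, 4219.

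With slide as a fixed block the counts were 15 at day 3, 12 at day 8, 127 in state 1 and 165 in state 2, and within single slides 17 (slide 2), 0 (slide 4), 1.3e+02 (slide 1, 47 higher and 79 lower) and 0 (slide 3). On each shared slide 1 of the 2 groups has a single array, so these values carry little weight. Adding the left-out array to the slide block gave 12, 17, 189 and 285, then 1157 over the span, where the proteasome and cell cycle medians turned positive (0.04 and 0.28), 23 for any state difference, 1096 for any day difference and 4 for the test of the difference; col-10 in state 3 turned to -0.079, and camera turned the direction of the early embryonic list in state 3 (adjusted p = 0.558), while its median stayed negative at -0.21. With slide as a random block, at a consensus correlation of -0.196, the counts were 1, 4919, 1897, 6863 and 3620 from day 3 to state 3, with 4177 for any state difference, 9997 for any day difference and 1872 for the test of the difference. Groups were clustered on slides, and a negative correlation then lowers the SE of group differences. These higher counts can come from that and are no evidence of a state difference. With the replicate block day 8 had 882 genes and the test of the difference 1; with the numbers of the value table day 8 had 1203 and state 3 had 394. With array position as a block state 1 had 36 genes. Without the 3 arrays of state 2 on slide 4, day 8 had 11, and its neuron, FLP and insulin-like calls ended.

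Leaving out 1 array at a time gave 0 to 1 genes at day 3, 0 to 3140 at day 8, 0 to 204 in state 1, 1777 to 4224 in state 2, 49 to 921 in state 3 and 8381 to 8928 over the span. Any state difference ranged from 0 to 1205 (without state 3 at day 8 replicate 4), any day difference from 2584 to 4655 and the test of the difference from 0 to 1. Each count of 0 is from limma, with 438, 4909 and 2617 genes at an unadjusted p under 0.05 as reported at day 3, day 8 and in state 1. The score difference ranged from 0.0581 to 0.111 at day 3, where it passed without state 1 replicate 1, from 0.0561 to 0.188 at day 8 and from 0.265 to 0.397 within state 2. The median of the ribosomal list at day 3 ranged from 0.0053, without state 2 replicate 3, to 0.157. It was positive throughout, although camera gave the other direction at 0.0053 (adjusted p = 0.943).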

Other observations

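The tests of array position and of a shared culture, for the closest pair of arrays, were chosen only after the result was seen. Several lists that camera did not call over the span had members that changed, as did many other genes. Of all 15519 genes 7029 rose and 2483 fell over the span, so the span counts here and in the next paragraph do not show a change particular to a list. Of 36 insulin-like peptide genes 18 rose and 4 fell (median 0.28, camera adjusted p = 0.415). Of 40 heat shock and chaperone genes 22 rose and 2 fell (camera adjusted p = 0.0994), of 25 antioxidant enzyme genes 13 rose and 3 fell (0.73), and of 16 DAF-16 induced genes, targets of the insulin pathway's transcription factor, 5 rose and 4 fell (0.227). Adjusted over the list alone these counts were the same. Of 36 germline genes 21 rose (0.0666), and of 44 respiratory chain genes 19 rose and 5 fell (0.963), 17 and 5 adjusted over the list alone.

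Nervous system genes moved both ways over the span, with 13 of 27 neuron genes higher and 5 lower (0.952), while 10 of 27 FLP neuropeptide genes rose (0.45), the same counts as adjusted over the list alone. Of 33 sperm genes 12 rose and 7 fell (0.263), of 35 early embryonic genes 14 rose and 4 fell (0.53), and of 26 oocyte genes 6 rose (0.952). Adjusted over the list alone these were 12 and 7, 13 and 4, and 2. The pharynx lists changed in few members: 3 of 13 muscle and gland genes rose and 2 fell (0.146), and of 11 genes of the abu family, which belong to the pharyngeal cuticle, 1 rose and 3 fell (0.0994). Adjusted over the list alone 2 rose and 2 fell in the first and 1 fell in the second. Within state 2, 27 of 171 detoxification enzymes rose and 23 fell, 15 of 145 collagens rose and 8 fell, and 7 of 40 heat shock genes rose. Of all 15519 genes 2570 rose and 1047 fell within state 2.

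Other splits of the same arrays were counted for each test, with missing values filled in. At day 8, 2 of 100 splits, the real one included, gave as many genes as the real 2151. The other, with state 3 replicate 4 placed among the state 2 arrays, gave 2705, and the count was 0 without state 2 replicate 3. Chance was thus argued against but not excluded. These splits did not keep slides apart: with slide as a block 12 genes passed at day 8 and 165 within state 2, each resting on 1 array of a group, and day 12 was alone on its slide. Slide therefore stays open for the counts below as well. Chance was also argued against within state 2, where 1 of 35 splits gave as many as the real 3620 (highest other 1999). The same held within state 3, 1 of 56 (680, highest other 44), and for any day difference, 1 of 100 (3811, highest other 834). These shares are the smallest that each set of splits can give and were not adjusted over the tests. Within state 1, 2 of 35 splits gave as many as the real 73, and the split that moved state 1 replicate 4 of day 3 to the other side gave 125, so chance was not excluded. Where the real count was 0 by limma, every split gives as many, so the splits say nothing about chance. This holds at day 3 (35 of 35, highest other 40; 438 genes at an unadjusted p under 0.05), for any state difference (97 of 97, highest other 1255; 3761) and for the test of the difference (97 of 97, highest other 298; 2647). Reassignments that called so many genes point to some structure among the arrays, which was not tested. The span allows 10 splits, too few for a share under 0.05; the real split gave 9518 genes and the highest other 1.

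The closest pair among all 276 pairs of arrays crossed states: replicate 1 of state 1 and replicate 1 of state 2, both at day 3, differed with an SD of 0.153 log2 units over 7170 genes, against 0.177 for the closest pair within a group. Their deviations from their group means were correlated across genes at r = 0.553. A shared position on the slides stays open. The other 3 such pairs of neighbouring slides had a median r of -0.0251 and a highest r of 0.169, and so few pairs cannot decide it. A culture shared by replicates of the same number may account for the close pair and also stays open, at a median r of 0.0989 over the other 7 same-numbered pairs. Each day 8 pair among them includes an array whose replicate number is in doubt. No biological explanation was tested.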
